A study of Homo sapiens with 6 samples.

How the data were processed

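RNA of human umbilical vein endothelial cells (HUVEC), primary cells that line a blood vessel, was measured on 6 Affymetrix Human Gene 1.0 ST arrays, which carry probes along the length of each transcript. Per the labels, 3 arrays held untreated cells and 3 held cells kept for 3 days with extracellular vesicles (called exosomes in the sample labels) of MDA-MB-231, a triple-negative breast carcinoma line. The vesicles were precipitated from concentrated conditioned medium with a polymer reagent, per the labels' protocols, and 300 ng of total RNA was labelled per array.

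The deposited table holds log2 expression values for 33297 probe sets. Affymetrix Expression Console and RMA (robust multi-array average: background correction, quantile normalisation and a summary per probe set) are named, without versions, in the submitters' processing notes. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. Values ran from 2.41 to 13.8 and none needed a further log transformation. The medians of the 6 arrays lay between 6.91 and 7.03, and their interquartile ranges between 3.01 and 3.32. The deposited distributions were therefore close but not identical, and the values were used as deposited. RMA places all arrays on one scale, so a shift of most transcripts in one direction would be partly removed from the measurements.

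Probe sets were named from the platform's annotation table. Of the 33297 rows, 19460 were paired with 1 gene symbol, 1754 with several and 12083 with none in the table used, and 19429 of those with 1 symbol matched a current RefSeq gene by Entrez Gene ID, which changed 0 symbols. Only rows with 1 symbol were named. Members of the gene lists without such a row were not analysed here. The 30% of all rows with the lowest mean over the 6 arrays, those under a mean log2 value of 5.79, were left out as dim. This left 15592 probe sets of 14763 genes. Where a gene had several probe sets, the one with the highest mean stood for the gene. Of 596 genes with several tested probe sets, 103 had at least 1 called, 43 had all called in 1 direction and 0 had calls in opposite directions. Probes of near-identical genes, such as metallothioneins, IFIT and OAS genes, can bind one another's transcripts, so values within such families are uncertain.

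The comparison of vesicle-treated with untreated arrays was a two-sided moderated test in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with a mean for each group, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested. A gene was called at an adjusted p under 0.05. Fold changes are differences of group means on the log2 scale, treated minus untreated, with the standard error (SE) of the moderated fit. Gene groups were 24 lists and 5 lists of cell type markers drawn from textbook knowledge. Each was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 29 lists, and again with an estimated correlation. The fry test asked whether a list's members moved, on balance, one way. The named genes were the 10 largest called rises and 10 largest called falls whose arrays did not overlap between groups, up to 4 members of each list in order of unadjusted p, and CD47, KDR and THBS1 in any case. XIST, TSIX and Y-linked genes were left out of the named genes and of the plot of all genes, but not of the tests and counts. The groups, tests, lists, naming rule and the alternatives below were chosen before the data were examined.

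The alternatives were no filter and a filter at 50% of rows, quantile normalisation between arrays, centring of each array on its median, eBayes with trend and robust options, array weights, the replicate number as a block, and leaving out each array in turn. Further alternatives were an added limit of 1 on the log2 fold change, an adjusted p under 0.1, limma's treat against a fold change of 1.2, and, for lists, fry and the mean of a gene's probe sets. The labels do not say that replicates came from separate cultures or lots, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision. A single value compared by an exact permutation of 3 against 3 arrays cannot reach a two-sided p under 0.1.

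The pipeline was tested on simulated data for this comparison, with 15592 probe sets. It recovered 77.6% of probe sets changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2. Of 197 simulated calls, 12 were false (6.09%). A planted list was called with an adjusted p of 9.49e-39 by camera and 0.00391 with an estimated correlation, and 0 of 28 random lists were called. The simulated genes varied independently of one another. In the real data the estimated correlation was 0.66 in the interferon list and 0.85 in the mitosis list. It was 0.0125 in the TGF-beta list, 0.0339 in the YAP and SRF list and 0.0348 in the oxidative stress list. The simulation therefore does not test list calls among correlated genes.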

Results

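The series measured gene expression in HUVEC that were left untreated (3 arrays) or exposed for 3 days to extracellular vesicles from MDA-MB-231 breast carcinoma cells (3 arrays). The comparison addresses how vesicles shed by carcinoma cells alter endothelial transcripts. Log2 expression values of replicate arrays correlated across probe sets with Pearson's r of 0.989 to 0.993 among untreated arrays and 0.995 to 0.996 among treated arrays, and between groups r was 0.982 to 0.991. Probe sets are not independent replicates. The first principal component held 64.4% of the variance and separated the groups. Untreated replicate 1 lay nearest to the treated arrays on it, at −11.9 against −23.9 and −21.9 for the other untreated arrays and 16.6 to 23.0 for the treated arrays.

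After exposure to the vesicles, 8 of the 10 genes with the largest rises belonged to the interferon response list, and SULF1, ITGA4 and TAGLN showed the largest falls. MX2, an interferon-induced GTPase that restricts viruses, rose 18.4-fold, from a log2 value of 6.88 ± 0.65 in untreated cells to 11.08 ± 0.19 in treated cells (SD, n = 3 each). LYVE1, the hyaluronan receptor of lymphatic endothelium, rose 14.8-fold, from 8.11 ± 0.29 to 11.99 ± 0.09. SULF1, which removes sulfate groups from heparan sulfate, fell 12-fold, from 10.95 ± 0.27 to 7.37 ± 0.17. ITGA4, the integrin alpha-4 subunit, fell 7.57-fold, from 9.07 ± 0.19 to 6.15 ± 0.03. In limma, the adjusted p was 1.27e-05 for MX2, 6.23e-07 for LYVE1, 8.29e-07 for SULF1 and 6.23e-07 for ITGA4.

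The other genes with the largest rises on the log2 scale were IFIT1 (3.93 ± 0.25, SE), RSAD2 (3.87 ± 0.22), IFIT2 (3.51 ± 0.16), CXCL10 (3.46 ± 0.29), IFIT3 (3.23 ± 0.21), PTPN22 (2.67 ± 0.11), OAS1 (2.63 ± 0.22) and EPSTI1 (2.55 ± 0.20). CXCL10 is a chemokine that attracts activated T cells, and PTPN22 is a phosphatase best known from lymphocytes. The largest falls also included TAGLN (−2.62 ± 0.17, SE), an actin-binding protein of smooth muscle, SHISA3 (−2.53 ± 0.13), the fatty acid carrier FABP4 (−2.31 ± 0.19) and the collagen gene COL12A1 (−2.16 ± 0.10). They were completed by the cadherin gene CDH6 (−2.13 ± 0.14), the elastic-fibre gene FBLN5 (−2.03 ± 0.11), the protease inhibitor SERPINE2 (−2.0 ± 0.18) and the growth factor TGFB2 (−1.98 ± 0.08). These 20 genes had adjusted p of at most 8e-05.

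**Figure D1:**
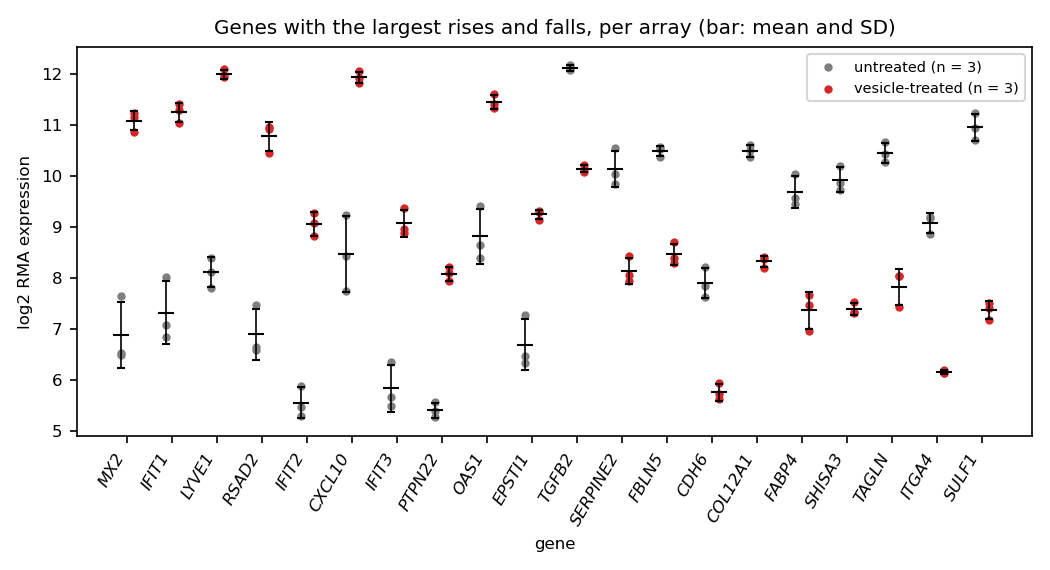
Log2 RMA expression (vertical axis) of the 10 genes with the largest rises and the 10 with the largest falls (horizontal axis), as 1 point per array for 3 untreated (grey) and 3 vesicle-treated (red) arrays, with the mean and SD as black bars. The groups do not overlap for any of the 20 genes, as the naming rule required, from MX2 (6.88 untreated, 11.08 treated) to SULF1 (10.95 untreated, 7.37 treated).

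In all, 2066 of 14763 genes (14%) were called, of which 1127 rose and 939 fell. Falls outnumbered rises after quantile normalisation (1170 rises, 1313 falls) and after centring each array on its median (689 rises, 732 falls). Among them, 118 rose and 76 fell at least 2-fold, and 22 rose and 9 fell at least 4-fold. The median absolute log2 change of the called genes was 0.48. The 3 treated arrays lay all above the untreated arrays for 1123 of the genes that rose and all below for 936 of those that fell. Over all genes, 31.7% had no overlap between groups, against 10% by chance. The number of calls fell to 1209 without untreated replicate 2, to 1011 without treated replicate 1 and to 1008 without treated replicate 2. The number of rises was 1993 without untreated replicate 1, 628 without untreated replicate 2, 719 without untreated replicate 3, 496 without treated replicate 1 and 544 without treated replicate 2, and the number of falls was 581 without untreated replicate 2 and 515, 464 and 536 without treated replicates 1, 2 and 3. Falls also outnumbered rises without untreated replicate 3 (1031 falls) and without treated replicate 1.

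**Figure D2:**
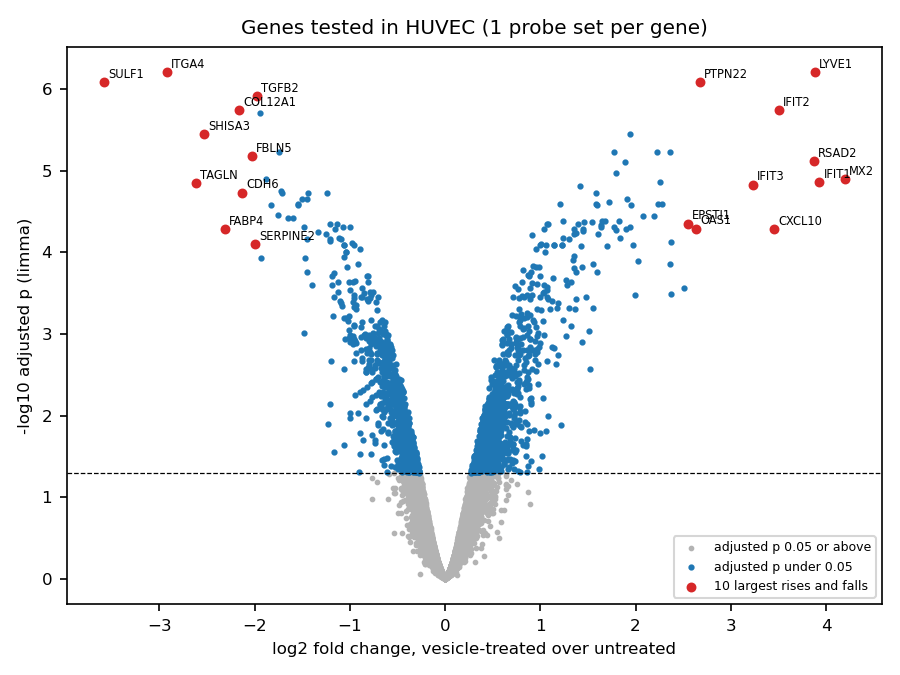
Log2 fold change of vesicle-treated over untreated cells (horizontal axis) against −log10 of the adjusted p from limma (vertical axis), 1 point per gene, with called genes in blue, other genes in grey and the 10 largest rises and 10 largest falls in red. XIST, TSIX and Y-linked genes are not drawn, but count among the 14763 genes tested and the 1127 rises and 939 falls called. Called genes lie above the dashed line at an adjusted p of 0.05.

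Interferon-induced genes rose together. Of 38 tested members of the interferon response list, 38 rose and 0 fell, by a median of 1.86 on the log2 scale, and 38 were called when adjusted over the list alone. Among them, OASL, a relative of the antiviral OAS enzymes, rose by 2.37 ± 0.13 (SE, adjusted p = 5.93e-06). In camera the list's adjusted p was 3.39e-42, and the adjusted p was 0.187 with an estimated correlation. In the list for antigen presentation by MHC class I, 11 of 13 tested members rose and 0 fell, with a median of 0.72, and 11 were called when adjusted over the list alone. PSMB9 (1.58 ± 0.11, SE) and PSMB8 (0.98 ± 0.10), subunits of the immunoproteasome, rose, as did the proteasome activator PSME1 (0.95 ± 0.12) and NLRC5 (0.72 ± 0.08), a transactivator of MHC class I genes. Each of PSMB8 and PSMB9 had 3 probe sets with the same fold change. The camera adjusted p was 6.97e-10, and the adjusted p was 0.187 with an estimated correlation. Untreated replicate 1 stood apart from the other untreated arrays in the interferon list, where its members lay on average −0.58 from their 6-array mean against −1.17 and −1.09 in untreated replicates 2 and 3.

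Genes of the TGF-beta response and of mesenchymal cells were lower as a list. Of 29 tested members, 0 rose and 12 fell (1 and 13 when adjusted over the list alone), with a median log2 change of −0.21. Besides TAGLN and TGFB2, these included CDH2, the gene of N-cadherin (−0.72 ± 0.08, SE), and SKIL, a repressor of SMAD-dependent transcription that TGF-beta itself induces (−1.01 ± 0.11). ACTA2, which is also in the fibroblast and smooth muscle list, went the other way (0.36) without a call. It was called as a rise under 5 of 13 alternatives. The TGF-beta list's camera adjusted p was 3.1e-09, and the adjusted p was 0.107 with an estimated correlation. Targets of YAP and SRF, transcription regulators that respond to cell tension and actin, were lower as a list, with 1 rise and 6 falls among 23 tested members (1 and 9 adjusted over the list alone) and a median of −0.17. They included the myosin light chain MYL9 (−0.77 ± 0.11), the LIM protein AJUBA (−0.64 ± 0.12) and endothelin-1, EDN1 (−0.52 ± 0.09). The camera adjusted p was 0.000156, and the adjusted p was 0.187 with an estimated correlation. The number of falls in this list was 3 without treated replicate 1 and 3 without treated replicate 2. Markers of fibroblasts, smooth muscle cells and pericytes included 0 rises and 3 falls among 12 tested, namely CNN1 (−0.69 ± 0.09), FAP (−0.63 ± 0.10) and THY1 (−0.66 ± 0.13), and the camera adjusted p of that list was 0.417.

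Genes of cholesterol and fatty acid synthesis were lower as a list. Of 22 tested members, 0 rose and 12 fell (0 and 15 adjusted over the list alone), with a median log2 change of −0.44. HMGCS1, which makes the precursor of mevalonate, fell 2.27-fold (−1.18 ± 0.13, SE), the fatty acid desaturase SCD 1.70-fold (−0.77 ± 0.10), lanosterol synthase LSS 1.61-fold (−0.69 ± 0.10) and fatty acid synthase FASN 1.49-fold (−0.57 ± 0.09). The camera adjusted p was 1.21e-12, and the adjusted p was 0.458 with an estimated correlation. In the list of oxidative stress genes and metallothioneins, 5 of 20 tested members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.23. These included mitochondrial superoxide dismutase SOD2 (1.79 ± 0.11), heme oxygenase HMOX1 (1.30 ± 0.15), the metallothionein MT1F (1.07 ± 0.11) and the quinone reductase NQO1 (0.76 ± 0.08). SOD2 is also a known target of NF-kB. The camera adjusted p was 4.1e-05, the adjusted p was 0.187 with an estimated correlation, and 8 members rose without untreated replicate 1.

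Genes of mitosis and G2/M were higher as a list, but the call of single members depended on which arrays were used. Of 33 tested members, 9 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 change of 0.57. CDK1, the kinase that drives entry into mitosis, rose by 1.22 ± 0.26 (SE, adjusted p = 0.0132), with an adjusted p of 0.0506 without untreated replicate 2 and 0.0581 without untreated replicate 3, over a range of 2.73e-05 to 0.0581 across alternatives. The camera adjusted p of the list was 5.96e-09, the adjusted p was 0.849 with an estimated correlation, and fry gave an adjusted p of 0.277. Without untreated replicate 1, 30 members rose. The number was 0 without untreated replicate 2, where 13 were higher at an unadjusted p under 0.05, and 0 without untreated replicate 3, where 11 were. It was 1 without treated replicate 1 and 3 without treated replicate 2. With each array centred on its median it was 3. In untreated replicate 1 the members lay on average 0.18 above their 6-array mean, within the range of the treated arrays (0.14 to 0.51), against −0.59 and −0.42 in the other untreated arrays. Treated replicate 1 was likewise the highest of its group (0.51 against 0.19 and 0.14). Of 35 tested genes of DNA replication and S phase, 2 rose (0 to 8 with 1 array left out) and 1 fell, and this list's camera adjusted p was 0.571, or 0.0184 without untreated replicate 1.

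Genes of VEGF, Notch and angiopoietin signalling were lower as a list, with 3 rises and 8 falls among 28 tested members (4 and 10 adjusted over the list alone), a median log2 change of −0.03 (0.01 without the filter on dim probe sets) and a mean of −0.17. The lymphatic VEGF receptor FLT4 fell 2.20-fold (−1.14 ± 0.09, SE), the Notch ligands JAG2 and DLL4 fell 2.01-fold (−1.0 ± 0.11) and 1.94-fold (−0.95 ± 0.12), and the growth factor PDGFB fell 1.45-fold (−0.54 ± 0.09). The list's camera adjusted p was 0.0220. It was 0.220 without untreated replicate 1, 0.224 with array weights, 0.229 in fry and 0.962 with an estimated correlation, over a range of 0.00382 to 0.962 across alternatives. KDR, the main VEGF receptor of blood endothelium, showed no call (0.05 ± 0.08, 95% interval −0.14 to 0.23, adjusted p = 0.785). In the lymphatic endothelium list, 1 of 8 tested markers rose (LYVE1) and 3 fell, including FLT4 and RELN (−1.19 ± 0.12), and the camera adjusted p was 0.0994.

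**Figure D3:**
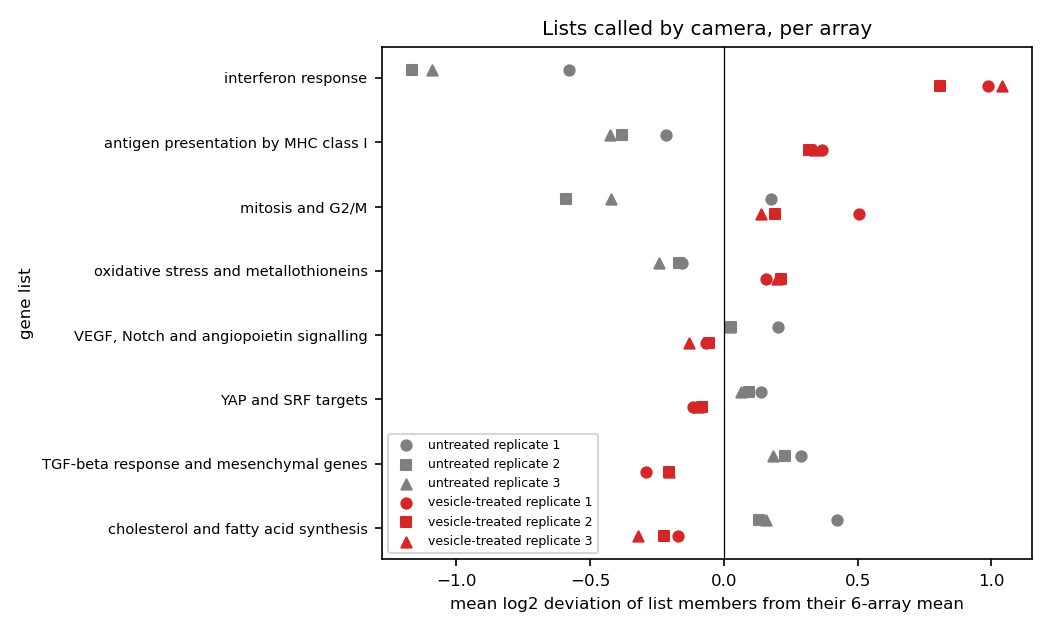
Mean log2 deviation of list members from their 6-array mean (horizontal axis) for the 8 lists called by camera (vertical axis), 1 point per array with 3 untreated (grey) and 3 vesicle-treated (red) arrays. The interferon list lies at −1.17 to −0.58 in untreated and 0.81 to 1.04 in treated arrays, and in the mitosis list untreated replicate 1 (0.18) lies among the treated arrays.

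The CD47, thrombospondin-1 and stemness list, which concerns the cell-surface receptor CD47 and its ligand, had 1 rise and 1 fall among 15 tested members (camera adjusted p = 0.860), and 1 to 3 rises and 0 to 1 falls with 1 array left out. CD47 rose 1.42-fold, from 10.07 ± 0.14 to 10.58 ± 0.02 (SD, n = 3 each; limma adjusted p = 0.00587). THBS1, the gene of thrombospondin-1, showed no call (−0.04 ± 0.08, SE, 95% interval −0.22 to 0.14, adjusted p = 0.834).

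Endothelial identity genes showed no shift as a list, with 3 rises and 3 falls among 28 tested members (camera adjusted p = 0.571). The sialomucin EMCN (−1.50 ± 0.10, SE) and the anticoagulant receptor THBD (−1.10 ± 0.13) were among the falls. Inflammatory adhesion molecules, chemokines and NF-kB targets went both ways, with 6 rises and 5 falls among 31 (adjusted p = 0.734), among them CCL5 (1.48 ± 0.17), CXCL6 (1.45 ± 0.12), IL6 (1.13 ± 0.12) and TNFSF15 (−0.89 ± 0.12). In the list for shear stress, nitric oxide and anticoagulant genes, 5 of 20 rose and 6 fell (adjusted p = 0.748), with a 3.85-fold rise of the prostaglandin synthase PTGS1 (1.94 ± 0.10) and falls of the nitric oxide receptor subunit GUCY1B1 (−0.82 ± 0.09) and of tissue plasminogen activator, PLAT (−0.70 ± 0.09). Basement membrane and matrix genes had 5 rises and 7 falls among 28 (adjusted p = 0.241; fry adjusted p = 0.0297), with falls of VCAN (−1.72 ± 0.11) and BGN (−0.61 ± 0.08) and a rise of NID1 (0.61 ± 0.10). Matrix proteases and their inhibitors had 5 rises and 4 falls among 20 (adjusted p = 0.860), with rises of cathepsin K, CTSK (1.40 ± 0.11), and MMP10 (1.00 ± 0.11) and a fall of MMP2 (−0.90 ± 0.08). With 1 array left out, rises ran from 0 to 5 and falls from 2 to 3 in the endothelial list, and rises ran from 4 to 7 and falls from 2 to 5 in the inflammatory list. They ran from 1 to 4 and 4 to 6 in the shear stress list, from 1 to 6 and 3 to 7 in the basement membrane list, and from 3 to 7 and 4 to 4 in the protease list.

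The remaining lists showed no call by camera. Hypoxia and glycolysis genes had 4 rises, among them HK2 (0.96 ± 0.14, SE), and 2 falls among 29 tested (adjusted p = 0.860). The lists of p53 targets (2 rises and 2 falls among 22, including PLK2, 0.86 ± 0.09, and GDF15, −0.66 ± 0.09), immediate early genes (3 and 3 among 20, including EGR1, 0.78 ± 0.10, and JUND, −0.44 ± 0.08) and heat shock proteins (1 and 2 among 12) had adjusted p of 0.860, 0.734 and 0.860. Unfolded protein response and ATF4 targets had 1 rise and 4 falls among 30 (adjusted p = 0.470), and lysosome and autophagy genes 0 and 5 among 21 (adjusted p = 0.178), including the lysosomal channel MCOLN1 (−0.76 ± 0.08). Genes of vesicle biogenesis and tetraspanins had 2 rises and 2 falls among 24 (adjusted p = 0.860), with CD82 up (0.60 ± 0.09) and CD151 down (−0.50 ± 0.09). Mitochondrial respiratory chain genes had 5 rises and 0 falls among 24, including NDUFB5 (0.97 ± 0.16), and cytosolic ribosomal protein genes had 2 and 0 among 24. Their adjusted p of 0.0994 and 0.105 became 0.00796 and 0.00796 without untreated replicate 1, and that of the respiratory chain became 0.0391 without treated replicate 3. Both lists were also called without the filter on dim probe sets (0.0372 and 0.0372) and with array weights (0.0373 and 0.0310). With 1 array left out, rises ran from 2 to 9 in the respiratory chain list and 0 to 4 in the ribosomal list. Rises and falls ran from 1 to 4 and 1 to 3 in the p53 list, 3 to 5 and 1 to 4 in the immediate early list, and 0 to 1 and 1 to 2 in the heat shock list. They ran from 3 to 5 and 1 to 3 in the hypoxia list, 0 to 2 and 1 to 4 in the unfolded protein list, and 1 to 4 and 1 to 2 in the vesicle biogenesis list. In the lysosome list they ran from 0 to 3 and 2 to 4, with 3 rises and 3 falls without untreated replicate 1.

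Markers of cells other than endothelium showed no call as lists. Markers of breast carcinoma and epithelial cells had 3 rises and 1 fall among 12 tested (adjusted p = 0.860), or 2 to 3 rises and 1 to 2 falls with 1 array left out, with KRT7 down (−1.55 ± 0.11, SE) and EGFR (0.61 ± 0.09) and KRT19 (0.42 ± 0.08) up. Leukocyte markers had 1 rise, the lysosomal protein CD68 (1.04 ± 0.11), and 1 fall (0 to 1 with 1 array left out) among 10 (adjusted p = 0.958). Markers of red cells and platelets had 0 rises and 0 falls in limma among 6 (adjusted p = 0.860).

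**Figure D4:**
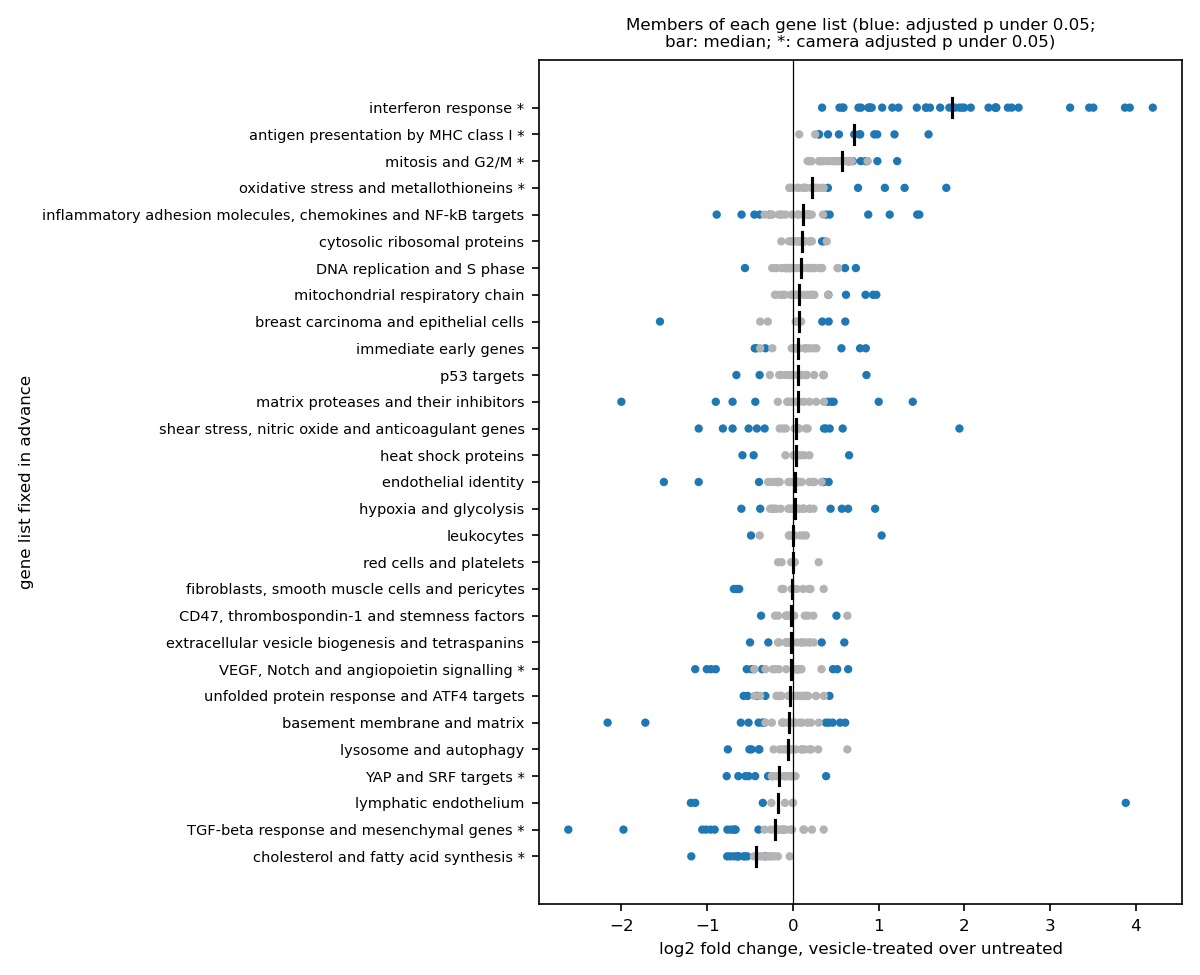
Log2 fold change of vesicle-treated over untreated cells (horizontal axis) for the tested members of 29 gene lists (vertical axis), 1 point per gene, blue where the gene's adjusted p was under 0.05, with the list median as a black bar and an asterisk for lists called by camera at the preset correlation. Medians run from −0.44 for cholesterol and fatty acid synthesis to 1.86 for the interferon response.

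Camera called 8 of the 29 lists, 4 up and 4 down, and fry called 7. With an estimated correlation camera called 0 lists, with 5 at an unadjusted p under 0.05. In the TGF-beta list the estimated correlation was 0.0125, near the preset 0.01, yet the unadjusted camera p went from 4.27e-10 to 0.00369. The loss of its call therefore cannot be laid to correlated members alone. Of the 8 lists, the 6 other than mitosis and VEGF signalling passed under each other alternative that was run, and mitosis passed under each but fry.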

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

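Counts of list members without single arrays or under other scalings were chosen after seeing the data, and the other alternatives before. The number of called genes, 2066, stayed within 1.5 times that value without the filter (1932), with the filter at 50% (1980), with quantile normalisation (2483: 1170 rises, 1313 falls), with median centring (1421: 689 rises, 732 falls), with trend and robust options (2194) and at an adjusted p under 0.1 (2906). Of the 2066 genes, 1994 were also called after quantile normalisation and 1420 after centring. Rises made up 54.5% of the calls as deposited, 47.1% after quantile normalisation and 48.5% after centring, so falls outnumbered rises under both, as they did without untreated replicate 3 (719 rises, 1031 falls) and without treated replicate 1 (496 rises, 515 falls). Array weights, which gave untreated replicate 1 a weight of 0.262 and treated replicate 2 a weight of 4.81, raised the calls to 4612 (2731 rises, 1881 falls). The cause was not tested for the drop in rises after centring or for the weights. A log2 change of at least 1 in addition left 194 genes (118 rises, 76 falls) and a test against a fold change of 1.2 left 464 (252 rises, 212 falls), both by construction stricter. Leaving out 1 array gave 1008 to 3078 calls, 496 to 1993 rises, 464 to 1085 falls and 8 to 10 lists, with the most calls without untreated replicate 1. Camera with an estimated correlation called 0 lists, and the other alternatives 7 to 10. Of the named genes, none that was called changed direction under these alternatives, and the median of the VEGF list was 0.01 without the filter. Among the named genes, 97 results lost and 6 gained a call when 1 array was left out, and 665 kept their side of the threshold. Dim transcripts near background were left out, and changes of 0.5 on the log2 scale were recovered less completely in simulation than changes of 1.

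With the replicate number as a block, the number of called genes was 2747 (1576 rises, 1171 falls), 27 of 33 mitosis genes rose and 8 lists were called. Deviations of samples with the same number correlated with r of 0.41, −0.01 and 0.15 across probe sets. The 0.41 of the replicate 1 samples was the highest of all pairs, while untreated replicate 2 correlated best with treated replicate 3 (0.27). With 3 arrays per group the deviations within a group depend on one another. These values therefore cannot decide whether equal numbers mark paired samples.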

Other observations

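The genes and families in the first 2 paragraphs were chosen for naming after their values were seen. Some were already counted in lists fixed in advance. IFIH1, RIGI and CXCL11 belong to the interferon list, CXCL2 to the inflammatory list and GDF15 to the p53 list. The RNA sensors IFIH1 (1.94 ± 0.16, SE, log2 scale), TLR3 (1.32 ± 0.14) and RIGI (1.23 ± 0.10) rose, while STING1, the adaptor of cytosolic DNA sensing, fell (−0.63 ± 0.11). Rises were also called for the inflammatory protease CASP1 (1.91 ± 0.13), the tryptophan-degrading enzyme IDO1 (1.89 ± 0.11), complement factor B, CFB (1.78 ± 0.10), and complement C3 (1.28 ± 0.14). The GTPase genes GIMAP4 (1.53 ± 0.24), GIMAP2 (1.44 ± 0.20) and GIMAP8 (1.33 ± 0.17) and the apolipoprotein L genes APOL1 (1.61 ± 0.14) and APOL6 (1.37 ± 0.14) rose as well. Outside immunity, TXNIP, which binds thioredoxin (2.26 ± 0.14), the adenylate kinase AK5 (2.23 ± 0.12) and the membrane peptidase MME (2.20 ± 0.17) rose. Falls were called for the Wnt agonist RSPO3 (−1.72 ± 0.12), the heparan sulfatase SULF2 (−1.55 ± 0.11), the BMP antagonist NOG (−1.48 ± 0.14), the Wnt receptors FZD3 (−1.48 ± 0.12) and ROR1 (−1.25 ± 0.08). Each of these genes was called in limma in 8 of 8 further settings: without each array in turn, with quantile normalisation and with median centring. These settings reused the arrays on which the genes were picked, so the calls are not independent support.

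Among 378 families of at least 6 tested genes that share a symbol stem, camera called 3 up and 4 down, and with an estimated correlation 0 (each adjusted p = 0.996). CXCL chemokines had 6 rises and 1 fall among 12 (median 0.28, adjusted p = 0.0197), including CXCL11 (2.51), CXCL2 (0.88) and CXCL16 (0.69), while CXCL12 fell (−0.68). This family overlaps the interferon list through CXCL10 and CXCL11. Small nucleolar RNAs of the SNORD class had 18 rises and 3 falls among 64 (median 0.19, adjusted p = 0.00570), including SNORD36B (0.91) and SNORD79 (0.92). The IFI family had 7 rises and 0 falls among 9 (median 0.80), and overlaps the interferon list. GDF growth factors had 0 rises and 4 falls among 7 (median −0.45, adjusted p = 0.0197, or 0.0568 after quantile normalisation), including GDF6 (−0.87) and GDF15 (−0.66). The OR family of olfactory receptors had 3 falls among 86 with a median of −0.14 over the family (adjusted p = 0.000275, 0.00138 after quantile normalisation and 2.24e-05 after centring). The KRTAP family had 2 falls among 49 (median −0.09) and the PCDHB family 3 among 9 (median −0.17), and both lost their call after quantile normalisation (adjusted p = 0.0547 and 0.138). Over all genes, 939 of 14763 were called as falls. The estimated correlation between members was 0.66 in the OR family and 0.65 in the KRTAP family. Whether the members of these 2 families lay near background was not tested. The medians kept their sign with quantile normalisation and with median centring in each of the 7 families.

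The tests of leukocytes and of fibroblasts were chosen only after the result was seen, and those of array splits, of brightness and of untreated replicate 1 before it. The rise of the interferon list was weighed first. Leukocytes in the treated cultures would raise their markers, but over 14 leukocyte markers without the filter the median log2 change was −0.0226 and the upper quartile 0.09, against 1.86 for the interferon list. These values do not exclude leukocytes too few to raise the markers. The markers with the highest log2 levels in treated cells moved apart, as CD68 (10.12) rose by 1.04 and LAPTM5 (10.66) fell by 0.49. After quantile normalisation the interferon median was 1.83, and genes matched on mean brightness had a median change of 0.02. The rise was therefore not shared by other genes of like brightness. Nor did it come from the small differences left between the deposited array distributions. Because RMA had already placed the arrays on one scale, these values cannot test for a difference in brightness before RMA. In the sample titles the numbering runs through all treated samples before the untreated ones. If it marks an order of handling, which is not stated, that order cannot be told apart from the treatment. It stays open whether the vesicles themselves, residual reagent of the precipitation or differences between HUVEC lots set off the response. The labels name no mock precipitate and do not state lots. A biological effect of the vesicles may therefore account for the rise, but was not tested.

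Untreated replicate 1 lay nearer to the treated arrays than the other untreated arrays did. If RNA of treated cells were mixed into it, genes that rose and genes that fell would be shifted alike. In 162 genes that rose at least 2-fold without this array the median shift toward the treated arrays was 17.1% (95% bootstrap interval 14.6 to 19.5). In 71 genes that fell it was −5.10% (−14.0 to 3.85). The bootstrap resampled genes, which are not independent, on 1 array. Its intervals therefore hold no spread between arrays. Its mean excess over the other untreated arrays in the interferon list was 0.55, and 0.52 after quantile normalisation, so the wider distribution of its values does not account for it. In the mitosis list the excess was 0.68 before and 0.69 after. Treated replicate 1 was also the highest treated array in the mitosis list (0.51 against 0.19 and 0.14). Whether the replicate 1 samples share a difference in mitosis genes was not tested. The shift of untreated replicate 1 toward the treated arrays was 14.7% in the interferon list. It was 18.3% (14.4 to 21.1) in 126 genes that rose at least 2-fold outside the interferon and mitosis lists. The shift was thus not confined to list members, but the 126 genes still held immune genes such as IDO1 and CASP1. They cannot show whether it went beyond the interferon response and mitosis, and no biological explanation was tested.

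The fall of TGF-beta and mesenchymal genes could come from fewer fibroblasts or smooth muscle cells in the treated cultures. Over 12 of their markers outside that list the median log2 change was 0.0130 and the lower quartile −0.16, against −0.84 for the list members that fell, which were picked because they fell (the whole list had a median of −0.21). In untreated cells 5 of the 12 markers lay below the level of the filter on dim probe sets. Of these, LUM (4.06) and DCN (4.48) were the dimmest, and POSTN (5.57) fell nonetheless (−0.73), as did THY1 (−0.66) and FAP (−0.63), which lay above it. Other markers above that level did not fall. The brightest, RGS5 (11.86), was higher by 0.19 and MYH11 (6.09) by 0.21, both without a call. These values do not decide the matter, and a loss of such cells and a change within the endothelial cells cannot be told apart here.

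The real grouping gave 2066 called genes, and 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many. The other splits gave at most 0 in limma, with 79 to 1570 genes at an unadjusted p under 0.05 against 3987 for the real split. With 10 splits the share cannot be under 0.05. Among rows with several gene symbols, 21 rose and 6 fell of 1469 tested, and among rows with no symbol in the table used, 70 rose and 36 fell of 6247 tested.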
